A study of Mus musculus with 16 samples.

How the data were processed

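RNA of 2 white fat depots was measured in mice that carry wild-type PPARg (WT) or are homozygous for PPARg-K107R, in which the lysine that accepts a SUMO group is replaced by arginine. Per the labels' protocols, mice ate chow for the first 10 weeks and a diet with 60% of its calories from fat for 19 weeks, and were then gavaged for 1 week with rosiglitazone, a PPARg agonist, at 10 mg/kg or with its vehicle, 1% methylcellulose. The depots are epididymal fat (eWAT) and inguinal fat (iWAT). Per the labels, depot, genotype and treatment make 8 groups of 2 libraries, 16 in all, each with replicate number 1 or 2. Libraries were made from 4 ug of total RNA with a stranded mRNA kit and read as 75-nt single ends, per the labels' protocols.

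The deposited table holds FPKM values for 14023 genes in 16 columns, and the authors' values were used as deposited. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.12, Cufflinks 2.2.1 and the mm10 build were used. The notes give neither the annotation, the strand setting, nor the scaling between libraries. Every gene reached 1 FPKM in at least 1 library. Since FPKM values carry no counts, the depth of each library is unknown and no counting interval or floor was computed. A value of exactly 0 is reported as listed at 0, with no fold against it. Of the symbols, 13520 matched the gene name table. Coordinates came from the mouse reference annotation on the same assembly as mm10. Members of gene families with near-identical copies (among them the Serpina1, Serpina3, Orm, Defb, Wfdc and Btnl genes), overlapping genes and the short RNAs Mir6974, Mir6392 and Snora70 can share reads with other genes, so their values are uncertain.

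Genes with at least 1 FPKM in at least 2 libraries were tested (13669 genes). Values were transformed to log2(FPKM + 1), which makes changes of genes with low values smaller. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 16 libraries, with a mean-variance trend, and gave each gene a log2 change, a moderated standard error (SE) and a two-sided p with Benjamini-Hochberg adjustment within each of 16 contrasts; a gene is called past the test at an adjusted p under 0.05. The contrasts were rosiglitazone against vehicle in each genotype, K107R against WT in each treatment, both averages and the interaction, in each depot, then eWAT against iWAT and the depot difference of the rosiglitazone response. Nothing in the labels says whether the 2 libraries of a group come from separate mice, or whether eWAT and iWAT come from the same mice, so p-values measure the spread between libraries, which may be technical.

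Before the data were examined, 28 gene lists were fixed, covering fat cell functions, signalling, inflammation and the markers of other cell types that a dissected depot can hold. Each list was tested with camera (limma) at a preset correlation of 0.01 between genes, with p adjusted over the 448 pairs of list and contrast; an estimated correlation and fry were the alternatives. With the preset correlation 211 pairs passed, and 68 of them also passed with the estimated correlation. A list result given without the second p is one of these 68 or did not pass the first test. Members past the test are counted over all genes tested and also adjusted over the list alone.

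The genes named were chosen by a rule fixed with the lists. For each contrast it takes up to 10 genes per direction with the largest log2 change among those past the test whose libraries do not overlap between groups and whose higher group mean is at least 2 FPKM, and up to 4 called members of each list. In a list with no called member it takes up to 2 with the smallest p, and where fewer than 5 genes were called in a direction, the 5 with the smallest p. Some genes that the rule takes are not reported here. Group values are the mean ± SD of FPKM with n = 2.

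The alternatives were a pseudocount of 0.1, no filter, rescaling each library by its median ratio to the geometric mean, and the depot's libraries alone. Further ones were library weights, the replicate number as a block, and leaving out each library in turn. Both libraries of each group got the same weight, from 0.452 in iWAT K107R vehicle to 2.65 in eWAT K107R rosiglitazone. The weights thus weigh groups and cannot mark a single poor library. Chosen after seeing the data were fits without the eWAT K107R vehicle libraries, without genes seen in those libraries alone, and without abundant genes listed at 0. Seen in those libraries alone means under 1 FPKM, or under 1% of the K107R vehicle mean, in every other eWAT library. The rule set no minimum in the K107R vehicle libraries and did not look at iWAT, so it also takes genes low in all of eWAT. Of 673 such genes tested, 58 reached 10 FPKM in both K107R vehicle libraries. The pairing comes from the replicate numbers of the labels, which do not say what a number stands for. Deviations from the group means correlated between same-numbered libraries in all 28 pairs of groups, with r from 0.121 to 0.791, so the numbers pair the libraries. The pairing is weak for eWAT K107R rosiglitazone, with r of at most 0.281 to any other group, against at least 0.501 in pairs without it. The block treats that group like the others and leaves its log2 changes as they were. Its contrasts may therefore keep part of the difference between numbers, with or without the block. For eWAT against iWAT and the depot difference of the response, the block had separate terms for each genotype and treatment. This pairs the same-numbered eWAT and iWAT libraries of a genotype and treatment, which the labels do not give as the same mouse. The values with the replicate block stand beside each count, of genes or of list members, that they moved by over 1.5 times: the eWAT WT rosiglitazone count, for example, was 61 without and 337 with the replicate block.

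The test was checked on simulated data for K107R against WT in vehicle eWAT over 13669 genes, with 100 genes changed by log2 1 and 100 by log2 2. The changed genes were drawn from those with a middle mean level. The shares recovered therefore do not cover genes with low or very high values. The measured shift between replicate numbers, averaged over all groups, was added to each group alike, which is what the block assumes. Then 23% and 62% were recovered without the block and 77% and 95% with it, with 0% and 3.37% false genes among those called. In the data the median shift was -0.183 in WT and -0.374 in K107R vehicle eWAT, so the shares with the block need not hold there. Without the added shift, the test recovered 24% and 73%, and 9.35% of its calls were false. Correlations across genes were set against 20 simulations of unchanged groups with the same shared libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 handled tables, exact tests and plots.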

Results

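The data are FPKM values in epididymal (eWAT) and inguinal (iWAT) fat of mice fed a high-fat diet, with WT or K107R PPARg and with rosiglitazone or vehicle, in 8 groups of 2 libraries. The files give no read counts, so the depth of each library is unknown. FPKM summed to between 411746 and 596519 per library, and between 11442 and 12898 genes reached 1 FPKM. The libraries with replicate number 2 had a lower median FPKM (5.36 to 7.92, and 8.83 in eWAT K107R rosiglitazone) than those with number 1 (8.95 to 9.61). The transcript of beta-actin, Actb, lay between 770.8 and 2016 FPKM in the number 1 libraries and between 21.7 and 261 FPKM in the number 2 libraries except that of eWAT K107R rosiglitazone, at 938 FPKM.

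Pparg (chromosome 6, 115360951 to 115490399, GRCm38) carries the mutation, which changes a residue and leaves no mark on a gene-level FPKM, so its level does not check the genotype labels. In eWAT, Pparg was at 89.4 and 73.4 FPKM in the WT vehicle libraries with numbers 1 and 2, 84.0 and 55.5 in K107R vehicle, 89.8 and 64.3 in WT rosiglitazone, and 97.2 and 78.6 in K107R rosiglitazone. In iWAT the values were 130.2 and 63.9 in WT vehicle, 143.8 and 65.0 in K107R vehicle, 138.8 and 74.2 in WT rosiglitazone, and 162.5 and 82.1 in K107R rosiglitazone. Of 23 genes of PPARg, its partners and the SUMO pathway, 1 rose with rosiglitazone in K107R eWAT (with the replicate block 1 rose and 1 fell; 1 adjusted over the list alone; list adjusted p = 0.72), and this was the fatty acid receptor Ppara (log2 0.71).

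Abundant fat cell genes were listed at 0 in whole groups. Fabp4, the fatty acid carrier of fat cells (chromosome 3, 10204088 to 10208576), was at 14168 to 23048 FPKM in 3 eWAT groups and listed at 0 in both K107R rosiglitazone eWAT libraries and in all iWAT libraries. The lipase Lpl was listed at 0 in the 4 rosiglitazone iWAT libraries and lay between 733.9 and 2423 FPKM elsewhere. The carbonic anhydrase Car3 was listed at 0 in all iWAT libraries except those of K107R vehicle, at 11260 and 5895 FPKM, and the desaturase Scd1 in all iWAT libraries except those of K107R rosiglitazone, at 2324 and 822.7 FPKM. No change is given for these 4 genes, although they are counted among the calls.

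The first question was what rosiglitazone did in WT eWAT. Rbp7, a retinol-binding protein of fat vessels (chromosome 4, 149449687 to 149454978), rose from 46.2 ± 7.24 to 268 ± 51.7 FPKM (mean ± SD, n = 2; log2 2.51 ± 0.25 SE, adjusted p = 0.0053). Spp1, osteopontin, rose from 87.1 ± 1.48 to 309 ± 0.701 (log2 1.82 ± 0.12, adjusted p = 0.00043), and Arg1, the arginase of macrophages, from 2.07 ± 0.432 to 10.8 ± 3.06. Gpd1 rose from 414 ± 3.8 to 766 ± 5.76 and Pck1 from 174 ± 6.67 to 306 ± 7.92. Both serve glycerol supply to triglyceride and belong to the list of PPARg targets and triglyceride storage genes. Sptlc3, a subunit of the first enzyme of sphingolipid synthesis, rose as well (log2 1.44), and so did the cytochrome Cyp4b1 (1.14). Of genes known from mast cells, the tryptase Tpsab1 rose from 12.2 ± 1.22 to 38.1 ± 1.96 and the IgE receptor chain Fcer1a from 5.37 ± 0.0312 to 13.3 ± 1.24, while the chymase Cma1 (log2 0.92, adjusted p = 0.056), Mcpt4 (0.97, adjusted p = 0.0634) and Tpsb2 (1.04, adjusted p = 0.184), chosen after their values were seen, passed only with the replicate block. Among genes that fell were Tph2, a tryptophan hydroxylase (log2 -1.50), Kcnj8, a potassium channel subunit of vessel walls (-1.40), the gelatinase Mmp9 (-1.35), the tubulin Tuba1a (-1.15) and the nucleic acid sensor Zbp1 (-1.12).

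Genes of fatty acid use were higher as lists. Of 18 genes of fatty acid oxidation, 0 passed over all genes, 8 with the replicate block, and 8 rose adjusted over the list alone (median log2 0.52, adjusted p = 1.7e-15). Among 24 PPARg targets and triglyceride storage genes, 2 rose and 0 fell, 8 rose with the replicate block, and 6 rose adjusted over the list alone (median 0.52, adjusted p = 2.5e-12). The 22 mitochondrial genes had a median of 0.28 with 0 past the test over all genes, 1 with the replicate block and 0 adjusted over the list alone (adjusted p = 6.2e-07), and adjusted p = 0.105 with an estimated correlation. Erythrocyte genes were higher, with Hba-a1 at log2 1.08, 4 with the replicate block and 5 of 5 adjusted over the list alone (median 1.12, adjusted p = 2.7e-11). B and plasma cell markers were lower as a list (0 of 10 past the test, 1 with the replicate block, 1 adjusted over the list alone, median -0.49, adjusted p = 3.9e-09, and adjusted p = 0.062 with an estimated correlation). So were T and NK cell markers (0 of 13, 1 with the replicate block, 2 adjusted over the list alone, median -0.24, adjusted p = 4.2e-07, and adjusted p = 0.072 with an estimated correlation). Lymph node stroma markers were lower as well (0 of 8, 2 with the replicate block, 0 adjusted over the list alone, median -0.60, adjusted p = 0.0025, and adjusted p = 0.074 with an estimated correlation). Interferon response genes were lower as a list (16 genes, 0 past the test, 3 with the replicate block, 1 fell adjusted over the list alone, median -0.46, adjusted p = 3.1e-10). Of 16 inflammatory mediators, 2 fell, Nos2 (-0.99) and Ccl8 (-0.84), 6 with the replicate block and 6 adjusted over the list alone (adjusted p = 5.4e-09, and adjusted p = 0.17 with an estimated correlation). Macrophage markers did not pass as a list (adjusted p = 0.42), with Spp1 the 1 of 21 that rose (1 rose and 1 fell with the replicate block, the same numbers adjusted over the list alone). Circadian clock genes had a median of 0.35 with 0 of 15 past the test, 2 with the replicate block and 0 adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.80 with an estimated correlation). In all, 61 genes passed, 23 that rose and 38 that fell, and 337 with the replicate block. The count fell whichever of the 4 libraries was left out, so the fall does not single out a library. Each omission leaves a lone library in its group and the replicate numbers out of balance. The count was 101 after rescaling, 1 with the depot's libraries alone and 289 with library weights.

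The same treatment in K107R eWAT asked how fat with the mutant receptor responded. Elovl3, a fatty acid elongase of brown fat (chromosome 19, 46131897 to 46135694), went from 1.64 ± 0.734 to 19.6 ± 1.39 FPKM (log2 2.99 ± 0.28, adjusted p = 5.8e-05). Ucp1, the uncoupling protein (chromosome 8, 83290352 to 83298452), went from 1.72 ± 1.0 to 19.6 ± 0.882 (log2 2.97 ± 0.45, adjusted p = 0.0022). Ehhadh, of peroxisomal fatty acid oxidation (chromosome 16, 21761287 to 21787807), rose from 16.1 ± 3.69 to 83.0 ± 1.86 (log2 2.31 ± 0.27). Ephx2, the soluble epoxide hydrolase, rose from 137 ± 37.9 to 648 ± 13.8, and Pdk4, a brake on glucose oxidation, by log2 2.06. The neutrophil genes S100a9 (log2 2.95) and Ngp (2.11) rose as well, S100a9 from 1.42 ± 0.259 to 17.8 ± 3.62 FPKM. The genes with the largest falls were secreted products of the epididymis that were high in the K107R vehicle libraries. Spint4 lay at 1176 ± 138 FPKM, Spink8 at 680 ± 83.2, Crisp1 at 504 ± 314 and Lcn5 at 440 ± 30.2 there. They fell by 8.38 (Crisp1) to 9.48 (Spint4) on the log2 scale.

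Of the fatty acid oxidation list, 10 of 18 rose and 0 fell, or 12 adjusted over the list alone (median 1.02, adjusted p = 1e-12), with Hadhb (1.27) and Acaa1b (1.27) among them. Brown and beige genes rose in 6 of 16, 10 with the replicate block, or 9 adjusted over the list alone (median 1.32, adjusted p = 1.9e-08), including Fabp3 (1.78) and Cox8b (1.44), with adjusted p = 0.08 with an estimated correlation. Mitochondrial genes rose in 5 of 22, 14 with the replicate block, or 10 adjusted over the list alone, with Cyc1 (0.75) among them; the list gave adjusted p = 6.1e-08, and adjusted p = 0.08 with an estimated correlation. Adiponectin, Adipoq, rose from 1133 ± 93.2 to 1987 ± 49.3 FPKM, Fgf21 rose (1.65), Rbp4 fell (-0.65), and 2 adipokines rose and 2 fell among 14 (3 and 2 adjusted over the list alone; list adjusted p = 0.53). Lipogenic genes split, with Acacb up (1.22), Thrsp (-1.48) and Fads2 (-1.65) down, 2 that rose and 3 that fell of 18, 5 and 5 with the replicate block, or 5 and 3 adjusted over the list alone (adjusted p = 0.57). Of 19 insulin signalling genes, Irs2 rose (1.07), 4 with the replicate block and 2 adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.78 with an estimated correlation). All 7 epididymis markers fell (7 adjusted over the list alone; median -5.92, adjusted p = 2.8e-33). So did 9 of 10 mammary and other epithelium markers (10 adjusted over the list alone; adjusted p = 4.9e-30), among them Krt18, from 35.03 ± 12.6 FPKM. Immediate early genes had 1 of 13 that rose, Fos (0.94), also adjusted over the list alone (1; 2 with the replicate block; list adjusted p = 0.63).

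In total 669 genes passed in K107R eWAT, 176 that rose and 493 that fell. With the replicate block 1494 passed, 690 that rose and 804 that fell. Leaving out 1 library gave between 80 and 129 that rose and between 365 and 418 that fell. Without genes seen in the K107R vehicle libraries alone, 302 passed, 126 that rose and 176 that fell. Rescaling moved the median log2 change of all tested genes from 0.17 to -0.01 in this contrast, and the medians of fatty acid oxidation and mitochondrial genes then were 0.83 and 0.40.

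**Figure D1:**
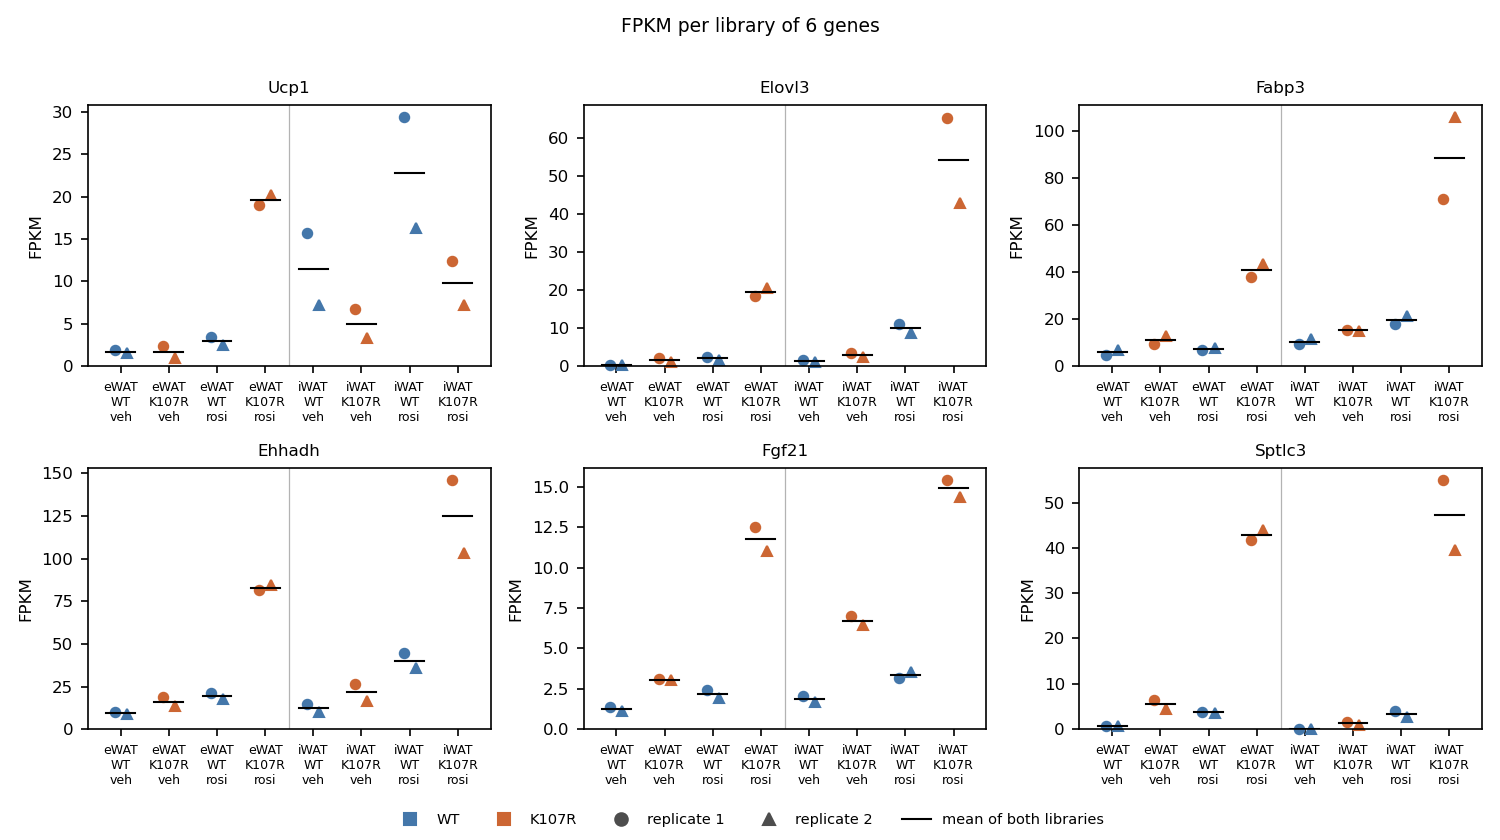
FPKM (vertical axes) of Ucp1, Elovl3, Fabp3, Ehhadh, Fgf21 and Sptlc3 in each library, by depot, genotype and treatment (WT blue, K107R orange; circles, replicate 1; triangles, replicate 2; black line, mean of 2). In eWAT the K107R rosiglitazone libraries lie highest for all 6 genes, with Ucp1 at 19.6 FPKM on average against 3.003 in WT rosiglitazone, while in iWAT Ucp1 lies at 9.81 FPKM in K107R and 22.8 in WT with rosiglitazone.

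Averaged over genotypes, rosiglitazone raised 218 genes and lowered 490 in eWAT (708 in all; with the replicate block 1594, of which 754 rose and 840 fell). With 1 library left out, between 120 and 195 rose and between 390 and 453 fell, and with library weights 369 and 601. Rbp7 (log2 2.18), Ephx2 (1.90), Ucp1 (1.76), the mitochondrial protein gene Chchd10 (1.47) and Spp1 (1.33) rose, and haptoglobin, Hp, fell by 1.87 together with Tph2 (-1.72), Igfals (-1.67), Kcnj8 (-1.52) and the matrix gene Comp (-1.72). Of the fatty acid oxidation genes, 10 of 18 rose, or 13 adjusted over the list alone (adjusted p = 4.4e-15). Collagen and matrix genes fell in 3 of 20 (with the replicate block 8 fell and 1 rose), or 3 adjusted over the list alone, with Thbs1 (-0.81) and Fn1 (-0.46) among them (adjusted p = 0.00048, and adjusted p = 0.185 with an estimated correlation). Fibroblast and progenitor markers fell in 3 of 13, 5 with the replicate block, or 4 adjusted over the list alone, led by Sfrp4 (-0.87) and Pi16 (-0.55) (adjusted p = 0.0009, and adjusted p = 0.50 with an estimated correlation). Without genes seen in the K107R vehicle libraries alone the count was 370, 173 that rose and 197 that fell, and 46 without those libraries; rescaling moved the median of all genes from 0.10 to 0.00.

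The next question was what the mutation did in eWAT without the drug. Plin5, which links lipid droplets to mitochondria, was at 6.3 ± 1.32 FPKM in WT and 37.8 ± 9.72 in K107R (log2 2.40). Sptlc3 was at 0.72 ± 0.048 and 5.47 ± 1.4 FPKM, the hormone Fgf21 (chromosome 7, 45613886 to 45615490) at 1.25 ± 0.181 and 3.05 ± 0.0308 (log2 0.85). Cyp4b1 was at 50.05 ± 1.39 and 92.0 ± 10.2, and Gpd1 at 414 ± 3.8 and 614 ± 3.12. Lower in K107R were Gdpd3, a phosphodiesterase of lysophospholipids (chromosome 7, 126766334 to 126775649; log2 -1.12), the acute phase gene Orm2 (-2.002) and Mmp9 (-1.18). Lower too were the plasma cell gene Mzb1 (-1.65), the killer cell gene Nkg7 (-1.34), the interferon-induced GTPase Igtp (-1.13) and the T cell kinase Lck (-1.02), while the leukocyte integrin Itgad was higher (1.35). The 10 genes with the largest changes are made in the epididymis or other epithelia and were Spint4, Spink8, Crisp1 (chromosome 17, 40293758 to 40319207), Lcn5, Spint5, Defb23, Defb22, Defb28, Wfdc10 and Cuzd1, with log2 changes from 7.84 (Cuzd1) to 10.15 (Spint4).

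Epididymis markers were higher in 7 of 7 (7 adjusted over the list alone; median 5.92, adjusted p = 3.1e-36), and mammary and other epithelium markers in 9 of 10 (10 adjusted over the list alone; adjusted p = 1.3e-30). Skeletal muscle markers were higher in 4 of 13, or 5 adjusted over the list alone, with Ckm at log2 1.15 (adjusted p = 2.1e-07). T and NK cell markers were lower in 5 of 13, 9 with the replicate block, or 8 adjusted over the list alone (median -0.62, adjusted p = 2.6e-08, and adjusted p = 0.056 with an estimated correlation). B and plasma cell markers were lower in 3 of 10, 8 with the replicate block, or 7 adjusted over the list alone (adjusted p = 3.7e-08, and adjusted p = 0.073 with an estimated correlation). Interferon response genes were lower as a list with 1 of 16 past the test, Gbp2 (-0.96), 10 with the replicate block and 1 adjusted over the list alone (median -0.67, adjusted p = 1.5e-06, and adjusted p = 0.067 with an estimated correlation). PPARg targets and storage genes were higher in 3 of 24, 5 with the replicate block, or 5 adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.24 with an estimated correlation). Counts were 395 genes higher and 63 lower, 458 in all, 1134 with the replicate block (652 higher, 482 lower) and 118 (90 higher, 28 lower) without genes seen in these K107R libraries alone. Leaving out 1 library gave between 319 and 364 higher and between 18 and 31 lower, and rescaling 480 and 124. Rescaling moved the median of all genes from -0.13 to 0.01, and the interferon median was then -0.55.

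With rosiglitazone, the genotype comparison in eWAT had little epididymal RNA on either side, with at most 0.851 FPKM of an epididymis list gene outside the K107R vehicle libraries. Sptlc3 (chromosome 2, 139493913 to 139637674) was at 3.67 ± 0.287 FPKM in WT and 42.8 ± 1.68 in K107R (log2 3.23 ± 0.23, adjusted p = 0.00012). Elovl3 was at 2.11 ± 0.512 and 19.6 ± 1.39 (log2 2.73 ± 0.28, adjusted p = 0.0011). Ucp1 was at 3.0 ± 0.65 and 19.6 ± 0.882 (log2 2.37 ± 0.45, adjusted p = 0.042), and the fatty acid carrier Fabp3 at 7.23 ± 0.643 and 40.7 ± 3.95 (log2 2.34). Ehhadh (2.05), Plin5 (2.01), Fgf21 (2.004) and S100a9 (2.46) were higher too. Lower in K107R were Tpsab1, at 38.1 ± 1.96 in WT and 2.43 ± 0.0864 in K107R (log2 -3.51), the mast cell chymase Mcpt4 (-1.22) and Gdpd3, at 75.2 ± 7.22 and 9.58 ± 1.05 (log2 -2.85). So were the lipogenic gene Thrsp (-1.99), the acute phase gene Saa3 (-1.50) and the retinol carrier Rbp4 (-1.21).

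Brown and beige genes were higher in 6 of 16, or 8 adjusted over the list alone (median 1.20, adjusted p = 1.9e-18), Cited1 (1.95) among them. Fatty acid oxidation genes gave 1 of 18 past the test, Ehhadh, 7 with the replicate block and 8 adjusted over the list alone (median 0.51, adjusted p = 3.5e-13). For 22 mitochondrial genes, 0 passed over all genes, 5 with the replicate block and 5 adjusted over the list alone (adjusted p = 5.7e-10, and adjusted p = 0.056 with an estimated correlation). The PPARg target and storage list had 3 higher and 1 lower of 24 (6 and 1 with the replicate block, 4 and 1 adjusted over the list alone), with a median of 0.44. Its mean of -0.08 was set by Fabp4 at 0 (adjusted p = 1.1e-06 upward, and adjusted p = 0.074 with an estimated correlation). Mesothelium markers were lower as a list, with Upk1b (-0.71) past the test, 3 with the replicate block and 8 of 9 adjusted over the list alone (adjusted p = 6.2e-14). Erythrocyte genes were lower, Hba-a1 by log2 -0.998, 4 with the replicate block and 4 of 5 adjusted over the list alone (adjusted p = 9.1e-08). Cholesterol synthesis genes had 0 of 17 past the test and 0 adjusted over the list alone (median 0.32, adjusted p = 0.021, and adjusted p = 0.75 with an estimated correlation). In all 124 genes differed, 76 higher and 48 lower, and 474 with the replicate block. The count was 55 without K107R rosiglitazone replicate 1, 50 without K107R rosiglitazone replicate 2, 50 without WT rosiglitazone replicate 1 and 42 without WT rosiglitazone replicate 2; it was 56 with the depot's libraries alone and 505 with library weights.

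Averaged over treatments, K107R eWAT had 453 genes higher and 135 lower (588 in all; with the replicate block 1627, of which 875 were higher and 752 lower). With 1 library left out, between 345 and 408 were higher and between 57 and 100 lower, after rescaling 508 and 224, and with library weights 570 and 287. Sptlc3 was higher (log2 2.56), and Tpsab1 (-2.15), Gdpd3 (-1.98), Orm2 (-1.59), Orm1 (-1.36), the chymase Cma1 (-0.94) and Rbp4 (-0.87) were lower. Macrophage markers were lower in 2 of 21, Aif1 (-0.74) and Fcgr1 (-0.74), 9 with the replicate block, or 7 adjusted over the list alone (adjusted p = 0.0001, and adjusted p = 0.56 with an estimated correlation). Cell cycle genes had 0 of 12 past the test, 2 with the replicate block and 0 adjusted over the list alone (median -0.23, adjusted p = 0.031, and adjusted p = 0.75 with an estimated correlation). The count was 233 (150 higher, 83 lower) without genes seen in the K107R vehicle libraries alone and 129 without those libraries.

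The interaction asked whether the rosiglitazone response of eWAT differed between genotypes. S100a9 (log2 2.87 ± 0.35, adjusted p = 0.00066), Ldoc1 (2.55), Elovl3 (1.805, adjusted p = 0.044), Fabp3 (1.51, adjusted p = 0.041), Mmp9 (1.30), the hedgehog receptor Ptch1 (1.18) and Fgf21 (1.15) responded more upward in K107R than in WT. The responses of Thrsp (-1.91), Hba-a1 (-1.52) and Spp1 (-0.98) were more downward. Brown and beige genes differed in 2 of 16, 5 with the replicate block, or 6 adjusted over the list alone (median 0.94, adjusted p = 1.7e-06, and adjusted p = 0.13 with an estimated correlation). For fatty acid oxidation 0 of 18 passed, 2 with the replicate block and 0 adjusted over the list alone (median 0.50, adjusted p = 8.5e-05, and adjusted p = 0.12 with an estimated correlation). All 7 epididymis markers differed (median -5.92, adjusted p = 9.3e-43), since they lay high in K107R vehicle. The interaction passed for 346 genes, 32 upward and 314 downward, for 574 with the replicate block (118 upward, 456 downward) and for 52 (10 and 42) without genes seen in the K107R vehicle libraries alone. With 1 library left out, between 14 and 21 were upward and between 266 and 318 downward, and with library weights 67 and 369. Rescaling moved the median of all genes from 0.15 to -0.02.

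In WT iWAT, the question was again what the drug did. Rbp7 rose from 87.9 ± 16.2 to 452 ± 92.9 FPKM (log2 2.35), Ephx2 from 106 ± 29.1 to 498 ± 99.6 (2.23), Elovl3 from 1.39 ± 0.496 to 9.96 ± 1.72 (2.204), and the peroxisomal thiolase Acaa1b (1.87) and Ehhadh (1.62) with them. Sptlc3 rose from 0.0768 ± 0.021 to 3.35 ± 0.815, and the nicotinic receptor gene Chrna2, known from beige fat, from 1.31 ± 0.0362 to 7.28 ± 0.478. Thbs1, a thrombospondin, fell from 38.2 ± 7.95 to 9.35 ± 1.64 (log2 -1.92), the monocyte chemokine Ccl2 from 17.0 ± 5.04 to 3.72 ± 0.589 (-1.91), and the peptide Apln (-1.70), the corepressor Hr (-1.64), Tph2 (-1.62), Pcdh12 (-1.60) and Kcnj8 (-1.60) fell.

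Fatty acid oxidation genes rose in 8 of 18, 14 with the replicate block, or 13 adjusted over the list alone (median 0.90, adjusted p = 7.8e-19). Mitochondrial genes rose in 3 of 22, 14 with the replicate block, or 10 adjusted over the list alone (median 0.65, adjusted p = 4e-16), with Mdh2 at 0.86. Lipogenic genes rose in 3 of 18, Acacb (1.29), Fasn (0.69) and Srebf1 (0.62), 8 with the replicate block, or 5 adjusted over the list alone (adjusted p = 0.00081, and adjusted p = 0.56 with an estimated correlation). Collagen and matrix genes fell in 3 of 20, 8 with the replicate block, or 6 adjusted over the list alone, with Col4a1 (-0.75) and Mmp14 (-0.70) (adjusted p = 7.4e-12). Endothelial markers fell in 1 of 13, Tie1 (-0.84) (with the replicate block 3 fell and 1 rose), or 1 adjusted over the list alone (adjusted p = 0.00091, and adjusted p = 0.061 with an estimated correlation). Lymph node stroma markers rose in 2 of 8, or 4 adjusted over the list alone (adjusted p = 1.4e-06), with Glycam1 going from 19.4 ± 4.97 to 60.4 ± 14.3 FPKM (log2 1.59). B and plasma cell markers rose in 2 of 10, 5 with the replicate block, or 3 adjusted over the list alone (adjusted p = 3.6e-07, and adjusted p = 0.094 with an estimated correlation). The count was 229, 123 that rose and 106 that fell (133 and 196 after rescaling), and 954 with the replicate block. It was 57 without WT vehicle replicate 1, 50 without WT vehicle replicate 2, 48 without WT rosiglitazone replicate 1, 52 without WT rosiglitazone replicate 2, 2 with the depot's libraries alone and 138 with library weights.

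In K107R iWAT, rosiglitazone raised Sptlc3 from 1.32 ± 0.506 to 47.2 ± 10.8 FPKM (log2 4.38) and Elovl3 from 3.0 ± 0.786 to 54.1 ± 15.9 (3.77). The lipid droplet enzyme Hsd17b11 rose from 58.2 ± 21.9 to 373 ± 82.3 (2.69), with the endothelial lipase Lipg (2.61), Chchd10 (2.53), Ehhadh (2.50) and Fabp3 (2.43). Tph2 (-2.45) and Serpina1b (-2.44) fell. So did transcripts of sperm and hair that were seen in K107R vehicle: Prm1 from 3.65 ± 0.594, Prm2 from 4.44 ± 0.571, Tnp1 from 4.64 ± 1.32 and the keratin Krt25 from 4.4 ± 0.0441 FPKM. Fatty acid oxidation genes rose in 9 of 18, 15 with the replicate block, or 13 adjusted over the list alone (median 1.00, adjusted p = 5e-18). Mitochondrial genes rose in 8 of 22, 17 with the replicate block, or 16 adjusted over the list alone (median 0.85, adjusted p = 3e-17), Cyc1 by 1.04. PPARg targets and storage genes rose in 7 of 24 (14 with the replicate block, 8 adjusted over the list alone), with Gpd1 at 1.19 and the lipase Pnpla2 at 1.14 (adjusted p = 1.3e-06, and adjusted p = 0.074 with an estimated correlation). The 1 counted lower there is Lpl, listed at 0 with rosiglitazone (1 adjusted over the list alone), which is not read as a fall. Adipoq rose by 0.85 among 16 genes linked to PPARg phosphorylation in obesity (2 higher and 4 lower with the replicate block, 1 higher and 3 lower adjusted over the list alone; list adjusted p = 0.071). The 1 counted lower over all genes is Car3, listed at 0 with rosiglitazone and not read as a fall either. Asns was the 1 of 14 unfolded protein response genes that rose (0.79; 1 adjusted over the list alone; list adjusted p = 0.63).

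Skeletal muscle markers fell in 8 of 13 in K107R iWAT, or 11 adjusted over the list alone (median -1.36, adjusted p = 2.4e-19), Acta1 from 40.7 ± 3.4 to 10.8 ± 1.88 FPKM. T and NK cell markers fell in 7 of 13, 11 with the replicate block, or 10 adjusted over the list alone (adjusted p = 5.6e-16). B and plasma cell markers fell in 6 of 10, or 9 adjusted over the list alone (adjusted p = 1.8e-14), with Cd79b at log2 -1.60. In total 263 genes rose and 312 fell (575 in all). With the replicate block the balance turned, with 904 that rose and 795 that fell (1699 in all). The count was 361 without K107R vehicle replicate 1, 342 without K107R vehicle replicate 2, 291 without K107R rosiglitazone replicate 1, 281 without K107R rosiglitazone replicate 2, 53 with the depot's libraries alone and 196 with library weights.

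**Figure D2:**
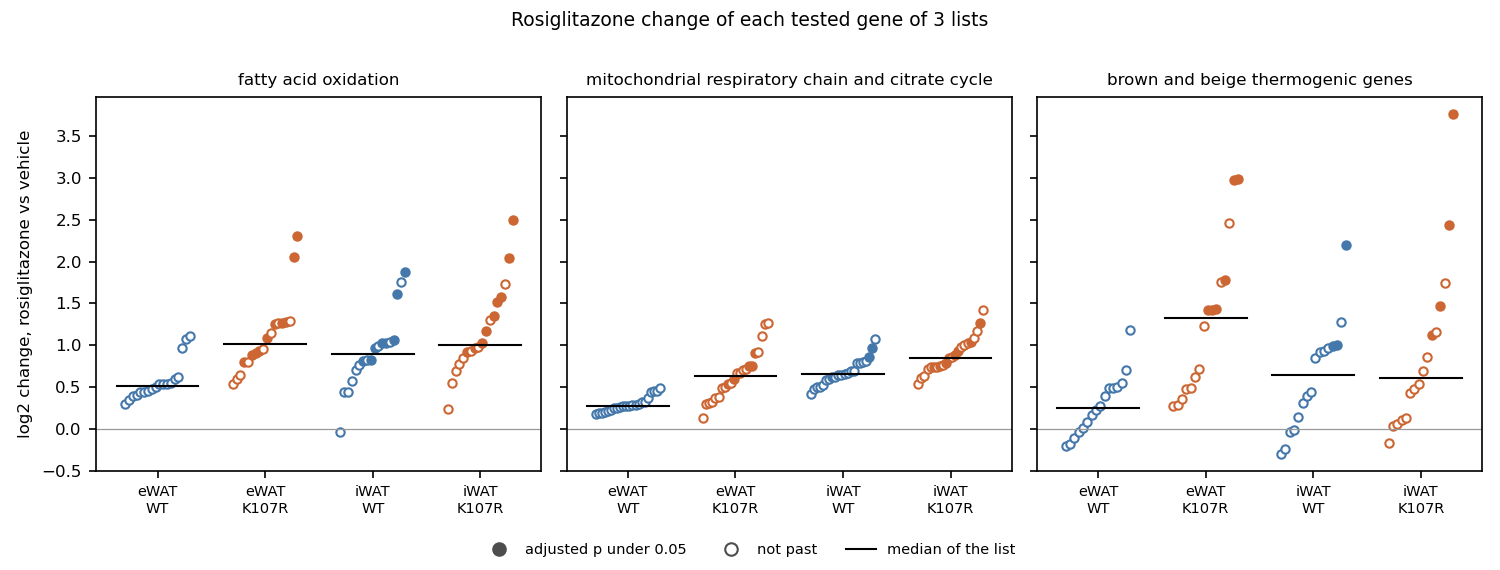
Log2 change with rosiglitazone (vertical axis, log2 of FPKM + 1) of each tested gene of 3 lists, fatty acid oxidation (18 genes), mitochondrial respiratory chain and citrate cycle (22) and brown and beige genes (16), in WT and K107R of each depot (filled points, adjusted p under 0.05; black line, median). The medians of fatty acid oxidation are 0.52 and 1.02 in WT and K107R eWAT and 0.90 and 1.00 in WT and K107R iWAT, and those of brown and beige genes 0.25, 1.32, 0.65 and 0.61.

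Averaged over genotypes, rosiglitazone raised 425 genes and lowered 308 in iWAT (733 in all; 420 and 621 after rescaling; 2210 with the replicate block). Sptlc3 (log2 3.19), Elovl3 (2.99), Rbp7 (2.36), Ephx2 (2.21), Lipg (2.07) and Ehhadh (2.06) rose, and Tph2 (-2.03), Thbs1 (-1.70), Kcnj8 (-1.66), Ccl2 (-1.62) and Igfals (-1.58) fell. Of the fatty acid oxidation genes, 12 of 18 rose, or 14 adjusted over the list alone (adjusted p = 1.8e-19), and 10 of 22 mitochondrial genes rose, 20 with the replicate block, or 18 adjusted over the list alone (adjusted p = 3.3e-19). Collagen and matrix genes fell in 7 of 20, 12 with the replicate block, or 10 adjusted over the list alone (median -0.47, adjusted p = 1.2e-10). The count was 479 without WT vehicle replicate 1, 488 without WT vehicle replicate 2, 478 without K107R rosiglitazone replicate 1, 476 without WT rosiglitazone replicate 1, 468 without WT rosiglitazone replicate 2, 207 with the depot's libraries alone and 386 with library weights.

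Without the drug, muscle genes were among those with the largest differences between K107R and WT iWAT. The creatine kinase Ckm was at 0.266 FPKM in WT and 10.6 ± 2.15 in K107R (log2 3.18), the troponin Tnnc2 at 1.87 ± 0.699 and 23.1 ± 7.69 (3.05), with Tnnt3 (3.03) and Tnni2 (2.73) higher as well. The leukocyte integrin Itgad (chromosome 7, 128154376 to 128223816) was at 8.59 ± 0.583 and 55.7 ± 2.5 FPKM (log2 2.56). Fgf21 was higher (1.43). Transcripts of sperm were higher too, Tnp1 (2.48) and Prm2 (2.44), and so were the hair keratins Krt25 (2.43) and Krt71 (2.18), chosen after their values were seen. The glutathione transferase Gsta3 was lower, at 16.7 ± 0.553 and 5.84 ± 0.505 FPKM (-1.37), as were the chemokine Xcl1 (-1.12), Kcnj8 (-0.94) and the inducible nitric oxide synthase Nos2 (-0.86).

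Skeletal muscle markers were higher in 10 of 13 genes of vehicle iWAT, or 11 adjusted over the list alone (median 2.02, adjusted p = 1.7e-69). B and plasma cell markers were lower as a list, with 0 of 10 past the test, 4 with the replicate block and 5 adjusted over the list alone (median -0.71, adjusted p = 1.2e-10). So were T and NK cell markers (0 of 13, 3 with the replicate block, 3 adjusted over the list alone, median -0.47, adjusted p = 7.9e-10). Interferon response genes were lower as a list (0 of 16, 3 with the replicate block, 3 adjusted over the list alone, median -0.51, adjusted p = 4.3e-09). Adipokines had Fgf21 as the 1 of 14 that was higher, 3 with the replicate block, 2 adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.60 with an estimated correlation). The comparison passed for 79 genes, 56 higher and 23 lower. The lower count was unstable, at 10 with a pseudocount of 0.1, 3 with library weights, 0 with the depot's libraries alone and between 3 and 9 with 1 library left out. With the replicate block it passed for 290, and the balance turned to 135 higher and 155 lower. It gave 34 without WT vehicle replicate 1, 38 without WT vehicle replicate 2, 38 without K107R vehicle replicate 1, 40 without K107R vehicle replicate 2, 136 after rescaling, 20 with the depot's libraries alone and 32 with library weights.

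With rosiglitazone, lymphoid transcripts were lower in K107R than in WT iWAT. Cd79b, a chain of the B cell receptor (chromosome 11, 106311341 to 106314762), was at 90.2 ± 19.98 FPKM in WT and 9.89 ± 1.58 in K107R (log2 -3.06), and the T cell kinase Lck was lower (-2.46). Glycam1, made by the high endothelial vessels of lymph nodes, was at 60.4 ± 14.3 and 5.43 ± 1.99 (-3.27). Higher in K107R were Sptlc3, at 3.35 ± 0.815 and 47.2 ± 10.8 (3.47), and Itgad, at 3.0 ± 0.338 and 42.5 ± 2.04 (3.45). So were Elovl3 (2.31), the sodium channel subunit Scnn1g (2.22), Fabp3 (2.10) and Fgf21 (1.87). The fatty acid synthase Fasn was lower, at 379 ± 26.6 and 168 ± 7.78 (-1.17), as was Thrsp (-2.16).

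B and plasma cell markers were lower in 9 of 10, or 10 adjusted over the list alone (median -2.50, adjusted p = 3.1e-27). T and NK cell markers were lower in 10 of 13, or 10 adjusted over the list alone (median -1.90, adjusted p = 6.7e-27), and lymph node stroma markers in 4 of 8, or 7 adjusted over the list alone (median -2.21, adjusted p = 1.4e-11). These lists held 22 of the 429 genes that were lower. Skeletal muscle markers were higher in 7 of 13, or 9 adjusted over the list alone (median 0.83, adjusted p = 3e-17). Brown and beige genes split into 3 higher and 1 lower of 16 (3 and 1 adjusted over the list alone), Elovl3, Fabp3 and Cited1 (0.87) above and Cox8b (-0.91) below, with a median of -0.05, a mean of 0.21 and an upward test at adjusted p = 0.34. Fatty acid oxidation genes had Ehhadh (1.60) as the 1 of 18 higher, 4 with the replicate block, and 1 adjusted over the list alone (adjusted p = 0.0064, and adjusted p = 0.28 with an estimated correlation). In all 565 genes differed, 136 higher and 429 lower, and 1280 with the replicate block; with library weights 90 were higher and 326 lower. The count was 357 without K107R rosiglitazone replicate 1, 356 without K107R rosiglitazone replicate 2, 365 without WT rosiglitazone replicate 1, 360 without WT rosiglitazone replicate 2 and 185 with the depot's libraries alone.

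**Figure D3:**
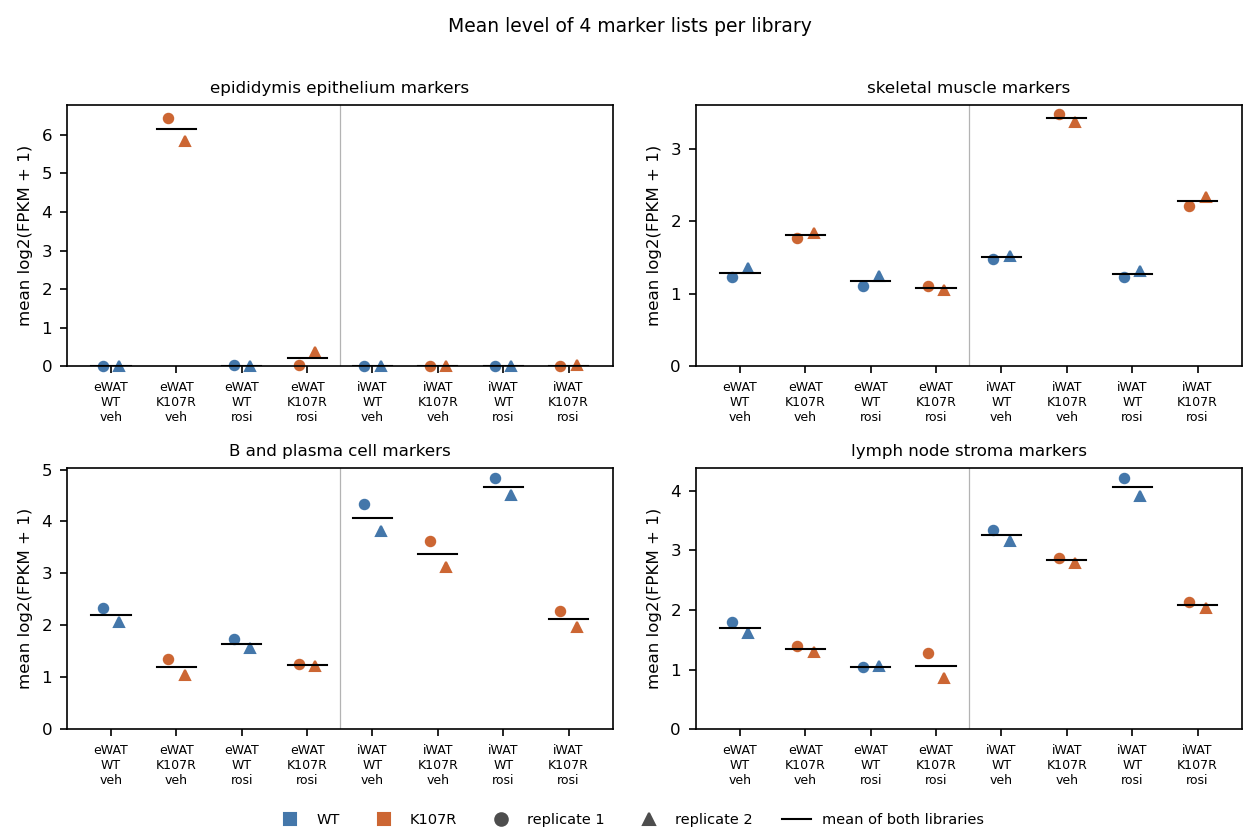
Mean log2(FPKM + 1) (vertical axes) of the epididymis, skeletal muscle, B and plasma cell and lymph node stroma marker lists in each of the 16 libraries (WT blue, K107R orange; circles, replicate 1; triangles, replicate 2). Epididymis markers are high in the 2 eWAT K107R vehicle libraries, muscle markers in the 2 iWAT K107R vehicle libraries, and the lymphoid lists lie lower in the 2 iWAT K107R rosiglitazone libraries than in the other iWAT libraries.

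Averaged over treatments, K107R iWAT had 184 genes higher and 457 lower (641 in all, 1514 with the replicate block, 183 with the depot's libraries alone and 409 with library weights; 292 higher and 498 lower after rescaling). Itgad (log2 3.005) and Ckm (2.61) were higher, and Cd79b (-1.90), the lymphotoxin gene Ltb (-1.74), Gdpd3 (-1.75) and Mzb1 (-1.66) lower. The mutation's interaction with the drug passed for 132 genes of iWAT, 11 upward and 121 downward, and for 346 with the replicate block (51 and 295). Upward and downward counts were 32 and 156 after rescaling and 6 and 100 with a pseudocount of 0.1. On the log2(FPKM + 1) scale, Sptlc3 (2.38), Scnn1g (1.48), Sbsn (1.30), the growth factor Bmp4 (1.08) and the mitochondrial carrier Slc25a34 (1.02) rose more in K107R. Glycam1 (-3.02), Ly6d (-2.63), Fcmr (-2.50) and Cd79b (-2.32) went the other way. In FPKM, Sptlc3 rose by no larger factor in K107R than in WT, where its vehicle value was very low. T and NK cell markers differed in 6 of 13, 10 with the replicate block, or 10 adjusted over the list alone (median -1.45, adjusted p = 4.8e-33), and skeletal muscle markers in 4 of 13, or 8 adjusted over the list alone (median -1.10, adjusted p = 4.7e-23). Fatty acid oxidation genes gave 0 of 18, and 0 adjusted over the list alone (median 0.18, adjusted p = 0.0053, and adjusted p = 0.27 with an estimated correlation). The interaction count was 76 without WT vehicle replicate 2, 77 without K107R vehicle replicate 1, 75 without K107R rosiglitazone replicate 1, 71 without K107R rosiglitazone replicate 2, 75 without WT rosiglitazone replicate 1, 78 without WT rosiglitazone replicate 2, 15 with the depot's libraries alone and 59 with library weights.

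The depots themselves were compared over all groups. eWAT had more of the mesothelial genes Upk3b (log2 4.55) and Msln (3.41), and of the macrophage genes Spp1 (4.38), Mmp12 (4.02) and Gpnmb (3.73). Group means of Gpnmb lay between 896 and 1193 FPKM in eWAT and between 58.3 and 104 in iWAT. iWAT had more of lymphoid genes such as Glycam1 (-4.01) and Cd79a (-3.08), and of Cidea (-1.98), Cox8b (-1.26) and Ucp1 (-1.20). Mesothelium markers were higher in eWAT in 9 of 9 (9 adjusted over the list alone, adjusted p = 3.3e-11). Macrophage markers were higher in 18 of 21 with 1 lower (18 and 1 adjusted over the list alone; median 2.26, adjusted p = 2e-10, and adjusted p = 0.24 with an estimated correlation). Cell cycle genes were higher in 11 of 12, or 12 adjusted over the list alone (adjusted p = 3.5e-05, and adjusted p = 0.38 with an estimated correlation). Endothelial markers were higher in iWAT in 9 of 13, or 11 adjusted over the list alone (median -0.62, adjusted p = 4.2e-07). Mitochondrial genes were higher in iWAT in 9 of 22, 18 with the replicate block, or 9 adjusted over the list alone (adjusted p = 7.6e-06, and adjusted p = 0.14 with an estimated correlation). PPARg targets and storage genes had a median of -0.59, a mean of 0.20 and a downward test, Fabp4 and Lpl being listed at 0 in iWAT groups (3 higher and 15 lower of 24, the same numbers adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.14 with an estimated correlation). The comparison passed for 4434 genes, 2720 higher and 1714 lower in eWAT. With the replicate block, which here pairs the depots, 4094 and 2469 passed, and after rescaling 2720 and 2706. Rescaling moved the median of all genes from 0.10 to 0.00.

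The last contrast asked whether the rosiglitazone response differed between depots. Spp1 (log2 1.30), Arg1 (1.51), the macrophage protein gene Cd5l (1.47), S100a9 (1.70), Hilpda (1.26) and the chemerin receptor Cmklr1 (1.01) responded more upward in eWAT. Epididymis markers differed in 6 of 7, or 7 adjusted over the list alone (median -2.96, adjusted p = 4.9e-37). Mitochondrial genes gave 0 of 22, 1 with the replicate block and 0 adjusted over the list alone (median -0.30, adjusted p = 4.2e-06, and adjusted p = 0.13 with an estimated correlation). The contrast passed for 302 genes, 38 upward and 264 downward, for 32 (13 and 19) without genes seen in the eWAT K107R vehicle libraries alone and for 6 without those libraries. With 1 library left out, between 23 and 43 were upward and between 211 and 275 downward, and after rescaling 58 and 277.

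Across the 13669 genes tested, which are not independent replicates, the rosiglitazone responses of WT and K107R correlated with r = 0.457 (rho = 0.547) in iWAT and r = 0.167 (rho = 0.267) in eWAT. Those of eWAT and iWAT averaged over genotypes correlated with r = 0.376 (rho = 0.48). Without genes seen in the eWAT K107R vehicle libraries alone or listed at 0, r was 0.492 in iWAT, 0.238 in eWAT and 0.517 between depots. Of the genes that rosiglitazone raised, 91 were shared between WT and K107R in iWAT, where 2.37 are expected by chance, with Elovl3, Rbp7, Gpd1 and Acadvl among them, and 15 in eWAT (0.296 by chance). In iWAT 73 fell in both genotypes (2.42 by chance) and 23 in eWAT (1.37 by chance). Calls in opposite directions were also seen in iWAT. There 19 genes rose in WT and fell in K107R (2.81 by chance), and 0 the reverse (2.04 by chance). All chance values given here take calls as independent, though every contrast uses the same estimate of a gene's spread. Part of each excess may come from that. Between depots 163 genes rose in both (6.78 by chance) and 139 fell in both (11 by chance). Among the latter were transcripts of sperm (Prm1, Prm2, Tnp1), epithelium (Krt5) and muscle (Myom2) that lay higher in K107R than WT vehicle in both depots. Genotype effects averaged over treatments correlated between depots with r = 0.282 (rho = 0.416), with 97 genes higher in both (6.1 by chance), and 71 lower in both (4.51 by chance), such as Gdpd3, Tpsab1 and Thrsp. If eWAT and iWAT come from the same mice, which the labels do not say, overlaps between depots in part repeat those mice and the chance values do not hold. Among the genes higher in both were Sptlc3, Itgad, Fgf21 and Plin5, and also transcripts of sperm (Prm1, Prm2, Tnp1), epithelium (Krt5) and muscle (Myom2). The effect of K107R in vehicle eWAT and that of rosiglitazone in WT eWAT share the WT vehicle libraries. They correlated with r = 0.207 and a covariance of 0.0393, against r = 0.49 and a covariance of 0.038 from unchanged groups that share those libraries. Without genes seen in the eWAT K107R vehicle libraries alone or listed at 0, r was 0.329 against 0.49 and the covariance 0.0424 against 0.039. In both, 6 genes rose (0.665 by chance), which were Chrna2, Sptlc3, Slc25a34, Cyp4b1, Pck1 and Gpd1, and 11 fell (0.175 by chance), Mmp9, Igtp and Nos2 among them. Higher in K107R and lowered by the drug were Serpina1b, Serpina3m and Serpina1d (1.1 by chance), and Tpsab1 went the opposite way (0.106 by chance). The chance values take the contrasts as independent. Part or all of the excess may come from the shared libraries, which are too few to split. Over all genes the covariance was close to that of unchanged groups. In iWAT the covariance was 0.0319 against 0.038, with 4 genes shared upward (0.504 by chance), Cacng5, Cyp4b1, Chrna2 and Marc1, and 10 downward (0.178 by chance). Another 3 were higher in K107R and lowered by the drug (0.434 by chance), and 2 the reverse (0.207 by chance). These shared genes were chosen after their values were seen.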

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

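The tests of epididymal, lymph node and replicate number explanations were chosen after the results were seen, as were leaving out genes seen in the eWAT K107R vehicle libraries alone and the splits balanced over the numbers for the depots; the other splits were planned.

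The rosiglitazone response of eWAT differed between genotypes in the interaction test for 346 genes. Among those named, S100a9 (log2 2.875), Ldoc1 (2.548), Elovl3 (1.805) and Fabp3 (1.506) rose in K107R by more than in WT. S100a9 is made by neutrophils, Elovl3 and Fabp3 serve fatty acid handling in brown fat, and Ldoc1 is a regulator of transcription. Without genes seen in the K107R vehicle libraries alone, a choice by their values that cannot show a source, 52 genes passed.

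Epididymis transcripts were seen in the eWAT K107R vehicle libraries, and all 7 epididymis list members tested passed in that interaction. Of the 7 members, 6 (85.7%) lay at 10 FPKM or more in both libraries, and none passed 0.851 FPKM in any other library. A genotype that turns these genes on in fat is argued against by the K107R rosiglitazone libraries, where the median member reached 0.129% of its K107R vehicle mean and the highest 1.15%. Libraries of another tissue are argued against by mesothelium markers, whose median log2 difference from WT vehicle eWAT was -0.0985, with members between -0.608 and 0.636. Epididymis tissue dissected with the fat may be the source, and whether it was present in 1 mouse or in 2 stays open.

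In iWAT the interaction passed for 132 genes, again in a test of the difference between genotypes. On the log2(FPKM + 1) scale, Sptlc3 (2.376), Scnn1g (1.48), Sbsn (1.304) and Bmp4 (1.082) rose more in K107R. Glycam1 (-3.025), Ly6d (-2.634) and Fcmr (-2.504) responded downward relative to WT. For Sptlc3 the difference depends on that scale, since its WT vehicle value was very low. In FPKM it rose by no larger factor in K107R than in WT.

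Lymphoid transcripts were lower in K107R than WT in rosiglitazone iWAT, and 3 of the downward genes named above are lymphoid, though skeletal muscle markers moved downward in the interaction too (median -1.10). A lower share of every cell type other than adipocytes is argued against by macrophage markers, with a median of 0.206 there, and by endothelial (-0.0807) and progenitor (0.125) markers. The lymph node stroma list and the B and plasma cell list both name Fcer2a, so they are not fully separate. Lymph node stroma markers had a median of -2.21, near those of B and plasma cell (-2.50) and T and NK cell markers (-1.90). Less lymph node in the dissected fat is therefore a candidate explanation. Fewer lymphocytes in K107R fat itself cannot be told apart from it, since the B and plasma cell median in rosiglitazone eWAT was -0.415, between the values that would have decided it, and that in vehicle eWAT was -0.902. Of the 429 genes that were lower, 412 (96.0%) also lay below 0 in vehicle iWAT, against 66.2% of all genes tested.

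The rosiglitazone response differed between depots, in a test of that difference, for 302 genes, with S100a9 at 1.702, Arg1 at 1.507, Cd5l at 1.468 and Spp1 at 1.297. Arg1, Cd5l and Spp1 are expressed by macrophages, and the test gave 32 genes without those seen in the eWAT K107R vehicle libraries alone. S100a9 had a genotype by treatment interaction of 2.875 in eWAT, so its average does not describe both genotypes. The other groupings given below do not exclude chance for this contrast.

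Libraries of replicate number 2 differed from number 1 in the same genes, but little in eWAT K107R rosiglitazone, where the median log2 difference was -0.029 against -0.175 to -0.528 in the other groups. Contrasts with that group may therefore keep part of the difference, and the block leaves their log2 changes as they were. Among them are rosiglitazone in K107R eWAT (669 genes), K107R in rosiglitazone eWAT (124) and the eWAT interaction (346). The difference correlated across genes with GC content, with rho between 0.253 and 0.562 over the 96.4% of genes that had a value. It also correlated with transcript length, with rho between -0.326 and -0.191. A difference between library or sequencing batches is a candidate explanation, but these correlations cannot tell it from other differences between the libraries. Muscle and epididymis scores matched within groups better than in other arrangements (exact permutation p = 0.00174 over 576 arrangements, the smallest they can give). The test was written after each list had been seen high in both libraries of a group, so this p carries little weight. Whether both libraries of a group share one tissue or RNA source cannot be told apart from an effect of the group itself, as each group has its own tissue.

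Other splits of the libraries were set against the real ones with limma for 2 groups. In eWAT rosiglitazone gave 4 genes and the highest other split 2, with 1 of 35 splits as large. Since the numbers pair the libraries, the 18 splits balanced over them are the closer comparison, and 1 of 18 is too few for a share under 0.05 (with the replicate block, 21 genes against at most 2). Genotype in eWAT gave 1 gene, the highest other split 4, and 10 of 35 were as large, so chance is not excluded. In iWAT rosiglitazone gave 163 genes and the split by replicate number 7990, so 2 of 35 splits were as large and chance is not excluded; this points to a structure of the samples that follows the number. Among the 18 splits balanced over the numbers, again too few for a share under 0.05, the real one alone was as large, and with the replicate block it gave 2023 genes against at most 62 in the others. Genotype in iWAT gave 0 genes by limma, so that all 35 splits were as large by construction, which says nothing about chance; with the replicate block it gave 62 genes against 2023 for the split by treatment. For the depots, 3985 genes passed against at most 3643 in the others, with 1 of 100 splits as large, so chance is excluded among those drawn. The split by replicate number, which was not drawn, gave 6746, a structure of the samples that follows the number. Over 100 splits balanced over the numbers the others gave 0. With the number alone as the block, without pairing the depots, 6108 genes passed against at most 158. For the depot difference of the rosiglitazone response, the real grouping gave 1 gene and the highest other 6621, with 11 of 100 as large, so chance is not excluded. Over 100 groupings balanced over the numbers the highest other was 760, with 19 as large. With the number alone as the block the real grouping gave 4 genes and the highest other 1899. Of 100 groupings, 5 were as large, so chance is not excluded there either. Groupings with many more genes point to a structure of the samples.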

How the results depend on the processing

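The tests without the eWAT K107R vehicle libraries, without genes seen in them alone and without abundant genes listed at 0 were chosen after the results were seen. The cause of the changes below was not tested, except where fewer libraries or genes were used. FPKM values carry no depth, so no limit set by depth is given.

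With the replicate block, rosiglitazone gave 337 genes in WT eWAT, 1494 in K107R eWAT and 1594 averaged in eWAT, and 954, 1699 and 2210 in iWAT. K107R against WT gave 1134 genes in vehicle eWAT, 474 in rosiglitazone eWAT and 1627 averaged, and 290, 1280 and 1514 in iWAT. The interactions gave 574 in eWAT and 346 in iWAT. Every gene called without the block within a depot kept its sign and its call with it. The block ended 5 list results, namely epididymis markers (adjusted p from 0.0419 to 0.145) and mammary and other epithelium markers (0.0343 to 0.0584) for K107R against WT in rosiglitazone eWAT. In iWAT these were adipokines for rosiglitazone in WT (0.0498 to 0.0512), lipogenic genes for rosiglitazone in K107R iWAT (0.0374 to 0.253) and genes linked to PPARg phosphorylation in obesity for rosiglitazone averaged in iWAT (0.0404 to 0.0942), and no other of the 211.

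With only the depot's libraries, rosiglitazone gave 1 gene in WT eWAT, 2 in WT iWAT, 53 in K107R iWAT and 207 averaged in iWAT. K107R against WT gave 56 in rosiglitazone eWAT, 20 in vehicle iWAT, 185 in rosiglitazone iWAT and 183 averaged in iWAT, and the iWAT interaction 15. The library weights were equal within each group, so they are no check on single libraries. Library weights gave 289 genes for rosiglitazone in WT eWAT, 505 for K107R in rosiglitazone eWAT, 138 and 196 for rosiglitazone in WT and K107R iWAT, 32 for K107R in vehicle iWAT, 59 for the iWAT interaction, and 386 and 409 for the averaged rosiglitazone and genotype contrasts in iWAT. Median-ratio rescaling gave 101 genes for rosiglitazone in WT eWAT, 20 of them among the 61, and 136 for K107R in vehicle iWAT, 47 of them among the 79. The other counts stayed within 1.5 times under rescaling, but their genes were partly replaced: 64 of the 124 called for K107R in rosiglitazone eWAT, 78 of the 229 and 292 of the 575 for rosiglitazone in WT and K107R iWAT, 74 of the 132 of the iWAT interaction and 368 of the 733 for averaged rosiglitazone in iWAT were kept. All 16 counts stayed within 1.5 times with a pseudocount of 0.1 or no filter, though the smaller direction did not with that pseudocount for K107R in vehicle iWAT (10 lower) and the iWAT interaction (6 upward).

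Without the eWAT K107R vehicle libraries, 46 genes passed for averaged rosiglitazone in eWAT, 129 for averaged genotype in eWAT and 6 for the depot difference of the rosiglitazone response. Genes seen in those libraries alone, by the rule given above, can include genes low in all of eWAT. Without them, 302 passed for rosiglitazone in K107R eWAT, 118 for K107R in vehicle eWAT and 52 for the eWAT interaction. The averaged rosiglitazone and genotype contrasts in eWAT gave 370 and 233, and the depot difference 32.

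Leaving out 1 library left a lone library in its group, assumed to vary like the others, and put the replicate numbers out of balance. The lowest and highest counts in eWAT were 1 and 4 for rosiglitazone in WT, 459 and 541 in K107R, 340 and 388 for K107R in vehicle, 42 and 55 with rosiglitazone, 281 and 339 for the interaction, 510 and 648 for averaged rosiglitazone and 403 and 496 for averaged genotype. In iWAT they were, in the same order, 48 and 57, 281 and 361, 34 and 40, 356 and 365, 71 and 117, 468 and 645, and 460 and 578. They were 3848 and 4559 between depots and 234 and 314 for the depot difference.

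The PPARg target and storage list, which holds Fabp4 and Lpl, had the opposite direction by fry from that by camera for K107R against WT in rosiglitazone eWAT (fry adjusted p = 0.0209) and between depots (0.0151). Of the 211 list results by camera, 126 also passed by fry, 124 of them in the same direction.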

Other observations

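The groupings of mast cell genes and of sperm and hair transcripts were chosen after their values were seen, and the 2 tests of rosiglitazone-raised genes were written earlier.

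Values of 4 genes known from mast cells, a group for which no list was tested, differed between genotypes in eWAT with rosiglitazone. Tpsab1 lay at 38.1 ± 1.96 FPKM in WT and 2.43 ± 0.0864 in K107R, Mcpt4 at 120 ± 15.9 and 50.7 ± 3.13, Cma1 at 82.4 ± 1.95 and 37.1 ± 3.61, and Fcer1a at 13.3 ± 1.24 and 5.6 ± 0.803. With vehicle the values were 12.2 ± 1.22 and 6.66 ± 1.11 for Tpsab1, 60.3 ± 2.55 and 41.2 ± 4.28 for Mcpt4, 43.0 ± 2.27 and 25.3 ± 1.09 for Cma1, and 5.37 ± 0.0312 and 3.13 ± 0.183 for Fcer1a. These genes encode granule proteases and the IgE receptor chain of mast cells. Other genes of that kind passed in K107R against WT with rosiglitazone only with the replicate block, Tpsb2 at log2 -0.84 (adjusted p = 0.317), Ms4a2 at -0.59 (adjusted p = 0.40) and Cpa3 at -1.30 (adjusted p = 0.91).

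Itgad, which pairs with Itgb2 on leukocytes, lay higher in K107R in both depots, at 12.9 ± 0.983 FPKM in WT and 34.4 ± 0.552 in K107R vehicle eWAT and at 8.59 ± 0.583 and 55.7 ± 2.5 in vehicle iWAT. With rosiglitazone it lay at 10.8 ± 1.21 and 44.2 ± 2.66 in eWAT and at 3.0 ± 0.338 and 42.5 ± 2.04 in iWAT. Transcripts of sperm were seen in K107R vehicle libraries of both depots, Prm1 at 37.7 ± 9.06 FPKM in eWAT and 3.65 ± 0.594 in iWAT, and Prm2 at 30.0 ± 2.11 and 4.44 ± 0.571.

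One hypothesis was that K107R enlarges the response of genes that rosiglitazone raises in the other depot. Of 218 genes raised in eWAT, 70.6% had an iWAT interaction above the median of all genes tested (median 0.175 against 0.0329). This passed the 60% set for the test and goes with a larger response in K107R iWAT. A different mix of tissues in the libraries cannot be told apart from that. T and NK cell markers and skeletal muscle markers moved downward in the same interaction. No share from unchanged groups was computed. If both depots come from the same mice, which the labels do not say, the choice of genes and the test share those mice. Of 425 genes raised in iWAT, 58.8% had an eWAT interaction above that median (0.22 against 0.151), short of the 60% set for the test, so a larger response in eWAT is not decided.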
